A study of Mus musculus with 40 samples.

How the data were processed

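The series holds RNA sequencing of striatum, the forebrain region that degenerates first in Huntington's disease, from mice of 6 months. Per the labels there were 5 genotypes with 8 libraries each, 4 from females and 4 from males: wild type, Alfy overexpression in the heterozygous state (Alfy het), the Q140 allele, and Q140 with Alfy overexpression in the heterozygous state (Q140 with Alfy het) or the homozygous state (Q140 with Alfy homo). Q140 is a knock-in of an expanded CAG repeat into the mouse huntingtin gene Htt. Alfy is the protein of Wdfy3, a large adaptor of selective autophagy. How the overexpression was made is not given in the sources used here. RNA was extracted with a column kit, libraries of poly-A RNA were made with a stranded kit, and fragments were read from both ends with reads of 100 bases.

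The deposited table holds counts, which the authors made per Ensembl gene. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq and the genome builds GRCm38 and mm10. Versions of STAR and HTSeq, the strand setting and the annotation release are not given in the sources used here. The values were whole numbers in all 40 columns, and 0 columns belonged to samples outside the labels. The table lists 48795 genes, of which 48349 were matched by identifier to GENCODE M21 on GRCm38 for symbols, positions, exonic length and GC content, and 446 were not. Totals per library ran from 44162204 to 65765919 counts, and intervals and spreads quoted here cover biological and counting variation between libraries only. Levels are CPM, counts scaled to the library total. Xist passed 100 CPM in 20 libraries, all 20 labelled female, and Ddx3y passed 10 CPM in 20 libraries, all 20 labelled male.

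Counts were tested with the quasi-likelihood test of edgeR 4.0.16 with robust dispersion, after filterByExpr by genotype with its minimum count of 10 and normalization by TMM. All 40 libraries entered 1 fit with genotype and sex as terms, and 20677 genes were tested. P values were adjusted by Benjamini-Hochberg over these genes and called at 0.05. Changes are log2 fold changes with a standard error (SE) that was derived from the fold change and its F statistic. CPM levels are given as mean and SD over 8 libraries. The comparisons were Q140 against wild type, Alfy het against wild type, Q140 with either Alfy genotype against Q140, the Alfy genotypes against each other, Q140 with Alfy het against Alfy het, and Q140 with either Alfy genotype against wild type, with interaction terms for Q140 and Alfy het and for sex.

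A total of 36 gene lists with 3 or more tested members, written as markers of cell classes and as pathways, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Signature scores were the mean, over signature genes, of the signed log2 CPM with a prior count of 2, centred per gene, and the groups were compared by an exact two-sided permutation test over 12870 splits of 16 libraries. Signature genes came from comparisons that share no library with the groups tested, because a comparison with Q140 against wild type and 1 with Alfy on Q140 share the Q140 libraries. Intervals of score differences are 95% bootstrap intervals from 10000 draws. Calls within 10 Mb of Htt or Wdfy3 were compared with calls elsewhere by Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over both genes and 8 comparisons. A scan of windows of 10 Mb, added to the planned tests, used the same test one-sided for more calls than elsewhere, adjusted over the windows of each comparison.

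Genes are named by a rule: in the 4 main comparisons, Wdfy3 and Htt, the 10 that rose and the 10 that fell most among called genes with a mean of at least 1 CPM and the same direction in males and females, and up to 4 members with the smallest p of each list that was called or had 3 or more called members. In the other comparisons the rule takes the 5 genes with the smallest p in each direction. Predicted genes, pseudogenes and genes without a symbol are counted and not named, with exceptions that the text marks as chosen after their values were seen. A few genes that the rule names are left out of the text because they were withheld. The comparisons, the tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were DESeq2 1.42.0, its size factors in edgeR, other filters, only the libraries compared, no sex term, each sex alone, each library left out in turn, and a block on the replicate number of the labels. Littermates were used, but no label ties a number to a litter, and libraries with the same number in different genotypes correlated no better than others (mean r 0.0197 over 80 pairs, range -0.618 to 0.645). The fit therefore had no block.

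Added after seeing the data were an offset for a per-library trend with transcript length and GC content fitted with mgcv 1.9.3, a covariate of cortical markers, a fit without 3 libraries that stood apart, a further signature, signatures from part of the Q140 libraries, and the interaction of Q140 and Alfy het in each sex alone and with no sex term. The 3 libraries were Alfy het F1 (choroid plexus genes), wild type M3 (thalamic genes) and Q140 with Alfy het M4 (second principal component). Alfy het F2 had nearly the same level of thalamic genes as wild type M3 (4.40 and 4.44 log2 CPM) and was kept, so this choice is not a consistent rule on thalamic genes. The steps were tested on simulated data with 20677 genes: of 50 genes changed 2-fold in 8 against 8 libraries, 48 were called, of 50 changed 1.25-fold 29 were called, 3 of the 189 genes called were unchanged, and 0 were called where no change was put in. These counts were drawn independently for each gene, without a trend or structure shared between genes. The share of false calls in the real libraries can therefore be higher. Other splits of the libraries were drawn at random, balanced for sex. At first 40 were drawn for every comparison, and after those were seen the number was raised to 100 for all of them with the same seed. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.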

Results

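RNA was measured in 40 striatal libraries from mice of 6 months, 8 per genotype, with 44162204 to 65765919 counts per library. The common dispersion over 20677 tested genes was 0.0181. Wdfy3 (ENSMUSG00000043940, chromosome 5, 101832956 to 102069921, GRCm38), which encodes Alfy, averaged 256 ± 13.5 CPM (SD, n = 8) in wild type, 225 ± 23.6 in Alfy het, 264 ± 30.9 in Q140, 220 ± 29.0 in Q140 with Alfy het and 213 ± 26.0 in Q140 with Alfy homo. It was therefore no higher in any of the 3 groups labelled with Alfy overexpression. By edgeR it fell in Q140 with Alfy homo against Q140 (log2 change -0.31, SE 0.08, adjusted p 0.0066). The changes were -0.26 (adjusted p 0.057) in Q140 with Alfy het against Q140 and -0.19 (adjusted p 0.130) in Alfy het against wild type. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) averaged 183 ± 9.69 CPM in wild type and 171 ± 10.6 in Q140, a change of -0.11 (adjusted p 0.262).

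**Figure D1:**
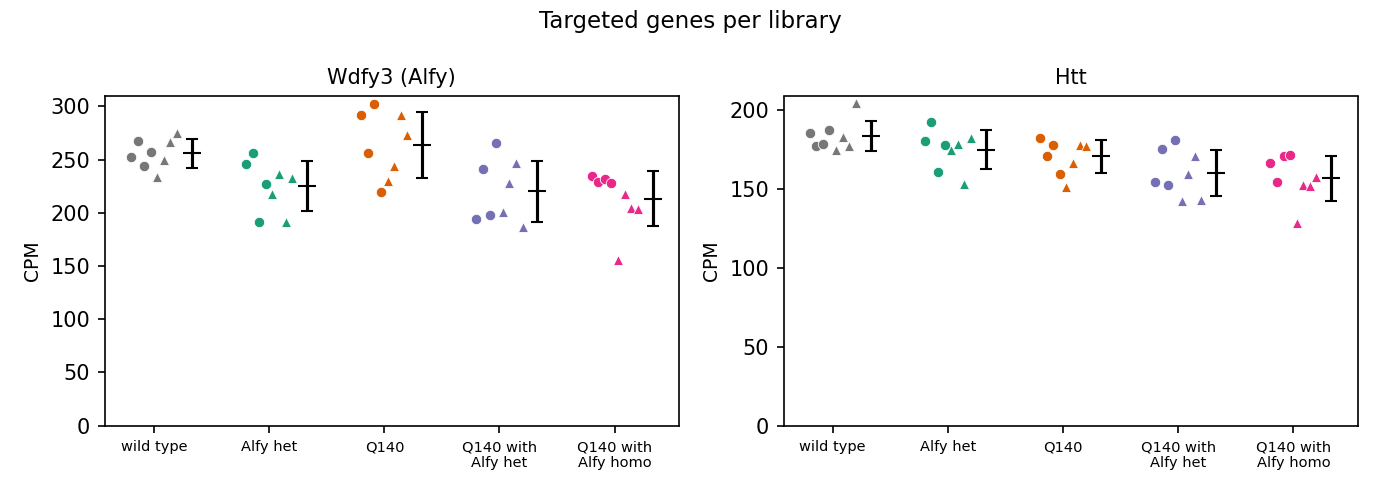
Levels of Wdfy3 and Htt in CPM for each of the 40 libraries by genotype, with circles for females, triangles for males, and the mean and SD of 8 libraries beside them. Wdfy3 averages 256 CPM in wild type and 213 CPM in Q140 with Alfy homo.

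Q140 was compared with wild type to ask what the expanded repeat changes in the striatum. Genes that mark striatal projection neurons, the main neurons of this region, fell together in Q140, both those shared by these neurons and those of the indirect pathway. Penk, which encodes the enkephalin precursor of indirect-pathway neurons, averaged 663 ± 116 CPM (SD, n = 8) in Q140 and 1452 ± 200 in wild type, a log2 change of -1.13 (SE 0.12, adjusted p 5.84e-08). All 8 Q140 libraries lay below the lowest wild type library for Penk, for Drd1, the D1 dopamine receptor (-0.66), for Scn4b, a sodium channel subunit (-1.14), and for Adora2a, an adenosine receptor of indirect-pathway neurons (-0.73). The edgeR fit called 1263 genes, 596 higher and 667 lower.

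**Figure D2:**
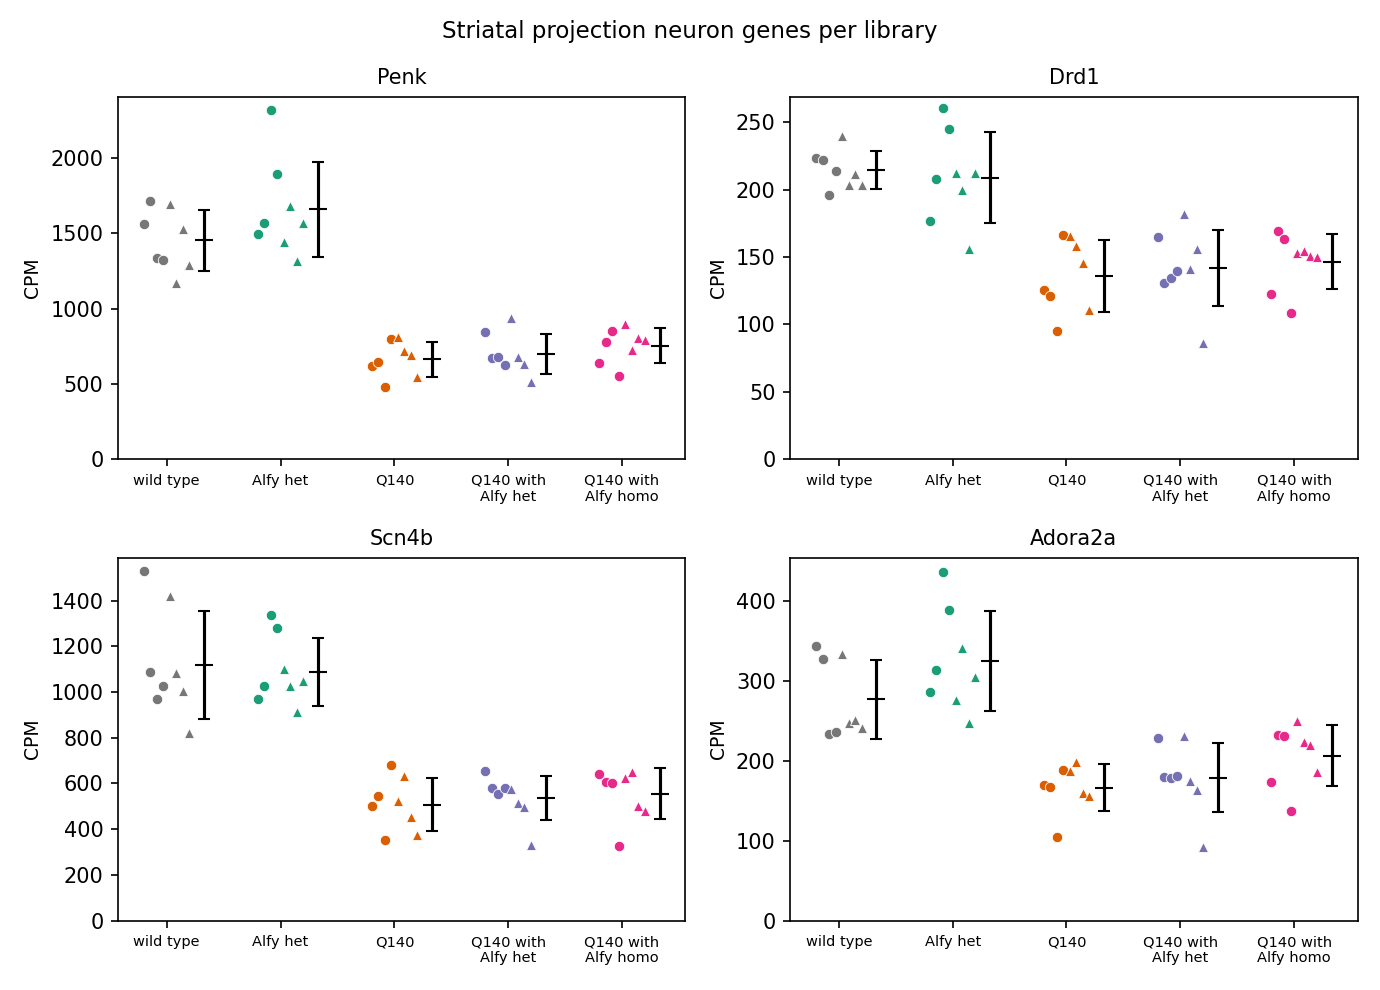
Levels of Penk, Drd1, Scn4b and Adora2a in CPM for each library by genotype, with circles for females, triangles for males, and the mean and SD of 8 libraries. Penk averages 1452 CPM in wild type, 663 in Q140 and 754 in Q140 with Alfy homo.

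Of 30 tested genes shared by projection neurons, 18 fell and none rose (24 adjusted over the list alone), with a median log2 change of -0.43. Among them were Ryr1, the skeletal-type ryanodine receptor (-1.17, SE 0.10), Cnr1, the CB1 cannabinoid receptor (-0.72, SE 0.08), and Arpp21 (-0.63, SE 0.09). The list was lower by camera (adjusted p 2.33e-37) and remained so with an estimated correlation (adjusted p 0.0479). Of 7 indirect-pathway genes 5 fell (5 adjusted over the list alone), including Gpr6 (-0.64) and Oprd1, the delta opioid receptor (-0.36), with adjusted p 5.16e-10 by camera and 0.0479 with an estimated correlation. Of 9 direct-pathway genes 3 fell (3 adjusted over the list alone), Chrm4, the M4 muscarinic receptor (-0.57), Drd1 and Sfxn1 (-0.21), and Isl1 was at 0.31 (adjusted p 0.217). That list had adjusted p 0.00759 by camera and adjusted p = 0.564 with an estimated correlation.

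Clustered protocadherins, cell adhesion genes of chromosome 18 expressed in neurons, rose in 14 of 58 and fell in 2 (21 and 4 adjusted over the list alone). Pcdhb3 rose by 0.81, Pcdhb5 by 0.53, Pcdhb22 by 0.49 and Pcdhb12 by 0.36, and neighbouring members of this family share sequence, so their counts are uncertain. The list had adjusted p 4.73e-07 by camera and adjusted p = 0.564 with an estimated correlation. Glutamate and GABA receptor genes fell in 4 of 27 (5 adjusted over the list alone), including Gabrd (-0.42), Grm5 (-0.33) and Grm3 (-0.27), with adjusted p 0.0075 by camera and adjusted p = 0.564 with an estimated correlation. Pericyte and smooth muscle genes fell in 3 of 8 (4 adjusted over the list alone): Kcnj8 (-0.43), Abcc9 (-0.35) and Tagln (-0.51), with adjusted p 0.000899 by camera and adjusted p = 0.234 with an estimated correlation. Of 14 myelin genes 2 fell, including Ugt8a (-0.38; 3 adjusted over the list alone), and of 13 microglial genes 1 fell (5 adjusted over the list alone). Both lists had adjusted p 0.000899 by camera, and with an estimated correlation adjusted p = 0.564 and adjusted p = 0.439. Of 31 core autophagy genes Atg4b (0.14) and Atg2a (0.13) rose and Atg14 (-0.15) fell, and that list was not called. Astrocyte genes averaged 7.45 ± 0.05 log2 CPM in Q140 and 7.57 ± 0.07 in wild type (n = 8) and reactive astrocyte genes 2.45 ± 0.10 and 2.69 ± 0.16, and thalamic genes had a median of -0.36. Of these lists, 2 of 11, 1 of 14 and 0 of 7 fell by edgeR (2, 2 and 0 adjusted over the list alone), with camera adjusted p 0.0119, 0.00384 and 0.0428, and with an estimated correlation adjusted p = 0.564, 0.281 and 0.585. Camera at its preset correlation also called endothelial (adjusted p 0.0407), immediate early (0.0362), cholesterol synthesis (0.0334) and interferon genes (0.0428) lower, and lysosome (0.0428), proteasome (0.000899) and oxidative phosphorylation genes (0.00357) higher. Of these 7 lists 0 to 2 members each were called by edgeR (0 to 3 adjusted over the list alone), and each had adjusted p = 0.564, 0.565 or 0.617 with an estimated correlation.

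The largest increases were Dsg1c, a desmosomal cadherin (1.14, SE 0.16), Tmc3 (1.07, SE 0.15), Dsp, which encodes desmoplakin (1.07, SE 0.28), Abhd1 (1.06, SE 0.12), Sfmbt2 (0.96), Vill (0.76), Pcdhb2 (0.74), Tnnt2 (0.71) and Pcdh20 (0.67). The largest decreases were Gpx6, a glutathione peroxidase (-2.35, SE 0.26), Wnt8b (-2.27, SE 0.37), Slc4a11 (-1.73, SE 0.14), Sec14l3 (-1.68), Vwa7 (-1.61), Fgf3 (-1.38), Odf4 (-1.35), Ptpn7 (-1.26), Serpinb1b (-1.25) and Cyp2a5 (-1.22). Of 220 tested genes within 10 Mb of Htt, 24 were called (10.9%, against 6.08% elsewhere, odds ratio 1.89, adjusted p 0.0421 by Fisher's exact test), and Abhd1, at 30950066 on chromosome 5, was 1 of them. In Q140 with Alfy het against Alfy het, which shares no library with this comparison, 9.55% of genes near Htt were called against 8.81% elsewhere (odds ratio 1.09, adjusted p 0.822). Calls near Htt were fewer than elsewhere in Alfy het against wild type (odds ratio 0.254, adjusted p 0.0421), and calls near Wdfy3 were fewer in Q140 with Alfy homo against wild type (18.6% against 29.7%, odds ratio 0.540, adjusted p 0.00321). With only 4 libraries per group, 195 genes were called in males alone and 193 in females alone.

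The Q140 change was measured again in libraries that the first comparison does not use, Q140 with Alfy het against Alfy het. There 1820 genes were called, 810 higher and 1010 lower. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated with r 0.573. Both comparisons called 214 genes higher and 421 lower, where 23.3 and 32.6 were expected by chance, and 1 gene was called in opposite directions. Projection neuron genes fell in 24 of 30 (28 adjusted over the list alone, camera adjusted p 1.65e-35, adjusted p = 0.0613 with an estimated correlation). The genes with the smallest p were Tmc3 (1.22), Vill (0.76), Wt1 (3.55), Tnnt2 (0.67) and Gfer (0.37) among those that rose, and Ddit4l (-1.28), Neto2 (-0.79), Slc4a11 (-1.52), Krt9 (-0.92) and Mafa (-2.29) among those that fell.

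Alfy het was compared with wild type to ask what the overexpression changes without Q140. Activity-induced genes, endothelial genes and chaperones were lower in Alfy het, and nuclear genes of oxidative phosphorylation and the proteasome were slightly higher, by camera at its preset correlation. Each of these lists had adjusted p = 0.56 with an estimated correlation, and 2 to 9 members of each were called. Nr4a3, an activity-induced nuclear receptor, averaged 13.1 ± 5.09 CPM (SD, n = 8) in Alfy het and 40.4 ± 21.7 in wild type, a log2 change of -1.59 (SE 0.37, adjusted p 0.0134). Flt1, a receptor of vascular endothelial growth factor, averaged 66.4 ± 5.58 CPM against 88.0 ± 6.98 (-0.41, SE 0.07). The edgeR fit called 1059 genes, 438 higher and 621 lower.

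Of 18 immediate early genes 3 fell (7 adjusted over the list alone), Nr4a3, Fosl2 (-1.28) and Fosb (-0.76), with adjusted p 6.84e-06 by camera. Of 10 endothelial genes 3 fell (4 adjusted over the list alone), Flt1, the transporter Abcb1a (-0.35) and the cadherin Cdh5 (-0.38), with adjusted p 2.65e-05. Of 15 chaperone genes the small heat shock gene Cryab (-0.58) and Hsph1 (-0.27) fell (11 fell adjusted over the list alone), with adjusted p 2.65e-05. Of 12 genes of the unfolded protein response Atf3 fell (-0.85; 3 adjusted over the list alone), with adjusted p 0.0454. Clustered protocadherins fell in 9 of 58 (16 adjusted over the list alone), including Pcdha8 (-1.40), Pcdhga7 (-0.63) and Pcdhga4 (-0.62), with adjusted p 3.16e-10. Oxidative phosphorylation genes rose in 9 of 40 (17 adjusted over the list alone), including Cox5b (0.21), Ndufb8 (0.19) and Sdhb (0.14), with adjusted p 6.19e-11. Proteasome genes rose in 3 of 31 (11 adjusted over the list alone), Psma7 (0.15), Psmd3 (0.12) and Psmd2 (0.10), with adjusted p 5.41e-06. Of 5 blood genes, 0 were called by edgeR, with a median of -0.38, camera adjusted p 0.0275 and adjusted p = 0.56 with an estimated correlation, as for the other lists here. Of 28 lysosome genes Lamp2 (-0.19) and Npc1 (-0.18) fell and Tfe3 (0.10) rose, and of 30 projection neuron genes 1 fell, and neither list was called.

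The largest increases were AA465934 (1.44, SE 0.36), the somatostatin receptor Sstr5 (1.44, SE 0.43), Oacyl (1.09), Fxyd2 (1.08), Ccer2 (0.95), Pdzd3 (0.81), Slc2a4, the insulin-responsive glucose transporter (0.76), Acr (0.73), Muc3a (0.72) and Rapsn (0.71). Besides Nr4a3 and Fosl2, the largest decreases were Mamdc2 (-1.22), Rnf125 (-1.16), Klf4 (-1.10), Upk1b (-1.08), Klf2 (-0.93), Thbs4 (-0.88), Btg3 (-0.86) and Atp6v0c (-0.81). Long transcripts were lower than short ones: across 15492 genes the change correlated with transcript length at rho -0.339, against -0.0689 in Q140 against wild type. The per-library slope of log2 CPM on log2 length averaged -0.00934 ± 0.0213 in Alfy het and 0.0276 ± 0.0157 in wild type (n = 8 each, exact permutation p 0.000466). With the added offset for length and GC content 640 genes were called, 530 of them among the 1059 in the same direction. Camera with that offset also called microglial genes lower (median -0.10, adjusted p 0.000269), with 0 of 13 called by edgeR. It called cholesterol synthesis genes lower too (adjusted p 0.0414), with 3 of 22 called. In males alone 59 genes were called and in females alone 8. The count was 557, 667 and 339 without Alfy het F3, M2 and M3, and 1607, 637, 627, 576 and 627 without wild type F1, F2, F4, M3 and M4.

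**Figure D3:**
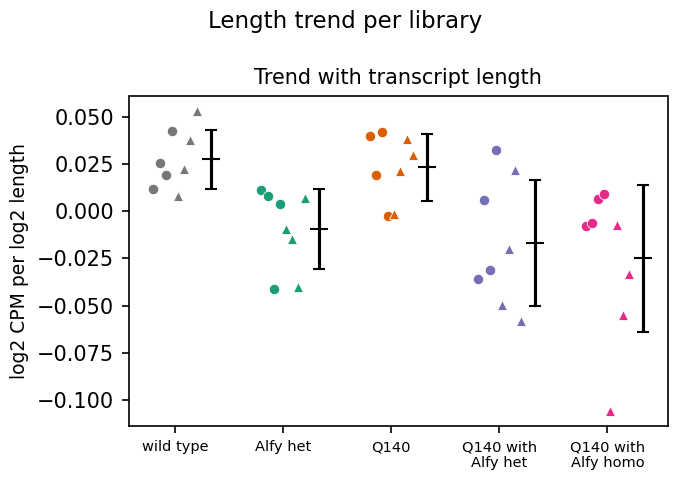
Slope of log2 CPM on log2 transcript length for each library by genotype, with circles for females, triangles for males, and the mean and SD of 8 libraries. The mean slope is 0.0276 in wild type, 0.0234 in Q140, -0.00934 in Alfy het, -0.0168 in Q140 with Alfy het and -0.0249 in Q140 with Alfy homo.

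Q140 with Alfy homo was compared with Q140 to ask what the homozygous Alfy genotype changes on the disease background. Endothelial, immediate early and protocadherin genes were lower, and genes of mitochondrial respiration slightly higher, by camera at its preset correlation. With an estimated correlation the endothelial list had adjusted p = 0.215 and the others adjusted p = 0.828, and the respiration calls ended with the added offset for length and GC content. With that offset 5 of 40 nuclear respiration genes still rose and 0 fell (median 0.05). Of 13 genes encoded in mitochondria 1 rose (median 0.16). The endothelial genes Flt1 (54.2 ± 5.94 CPM against 77.1 ± 6.71, n = 8 each), Cdh5, Abcb1a and Kdr fell by 0.51, 0.53, 0.49 and 0.65 on the log2 scale. Crocc, which encodes the ciliary rootlet protein rootletin (chromosome 4, 141016637 to 141060550), averaged 40.7 ± 4.11 CPM against 96.9 ± 8.44 (-1.25, SE 0.09, adjusted p 7.04e-12), and all 8 libraries lay below every Q140 library. The edgeR fit called 2780 genes, 1432 higher and 1348 lower.

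Of 10 endothelial genes 6 fell (6 adjusted over the list alone, adjusted p 1.28e-07 by camera, adjusted p = 0.215 with an estimated correlation). Of 18 immediate early genes 7 fell (10 adjusted over the list alone), including Egr2 (-1.54), Egr1 (-0.72), Fosb (-0.59) and Egr3 (-0.52), with adjusted p 1.67e-05. Clustered protocadherins fell in 17 of 58 and rose in 1 (23 and 1 adjusted over the list alone), including Pcdha12 (-0.80), Pcdhb2 (-0.79), Pcdhga4 (-0.62) and Pcdhgc5 (-0.42), with adjusted p 2.19e-09. Of 15 chaperone genes Hspa8 (-0.49) and Hspb1 (-0.70) fell (9 adjusted over the list alone), with adjusted p 0.00166. Oxidative phosphorylation genes rose in 11 of 40 and fell in 1 (18 and 1 adjusted over the list alone), including Sdhb (0.25), Cox4i1 (0.18) and Uqcrfs1 (0.14), with adjusted p 1.12e-06, and this call ended with the offset for length and GC content (adjusted p 0.914). Of 13 genes encoded in mitochondria mt-Co3 (0.28), mt-Nd1 (0.22) and mt-Cytb (0.17) rose (7 adjusted over the list alone), with adjusted p 0.00123, and adjusted p 0.158 with that offset. This list averaged 9.01 ± 0.17 log2 CPM against 8.83 ± 0.08 in Q140 without the offset (n = 8). With it the median log2 change was still 0.16. Proteasome genes rose in 5 of 31 (5 adjusted over the list alone), including Psmb3 (0.20), Psma4 (0.14) and Psma7 (0.13), with adjusted p 0.0216, and adjusted p 0.943 with that offset. Glutamate and GABA receptor genes fell in 4 of 27, including Grm7 (-0.32) and Gria2 (-0.20), and Gabrd rose (0.25; 4 and 1 adjusted over the list alone), with adjusted p 0.0361, and adjusted p 0.360 with that offset. Of 5 blood genes 0 were called by edgeR, and their list had camera adjusted p 0.219, and 0.00681 (lower) with that offset. Each list of this paragraph called at the preset correlation, other than the endothelial list, had adjusted p = 0.828 with an estimated correlation.

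Of 31 core autophagy genes Gabarap (0.21), Atg10 (0.22) and Map1lc3a (0.17) rose and Rb1cc1 (-0.22) fell (4 and 2 adjusted over the list alone). Of 14 selective autophagy receptors Phb2 (0.12) and Calcoco1 (0.14) rose and Ncoa4 (-0.22) fell (4 and 1 adjusted over the list alone). Of 28 lysosome genes Lamp2 (-0.16), Atp6v1h (-0.16) and Grn (-0.10) fell and Npc2 (0.16) rose. In the unfolded protein response Atf4 (0.29) and Ddit3 (0.29) rose, and the chaperone Hspa5 (-0.53) and Herpud1 (-0.24) fell. None of these 4 lists was called by camera, but with the added offset core autophagy was called higher (adjusted p 0.0451) and the unfolded protein response lower (adjusted p 0.0201). Camera with that offset also called the interferon list lower (adjusted p 0.0338), with 0 of 11 genes called by edgeR. Of 30 projection neuron genes 1 fell and none rose, with a median of 0.10 (camera adjusted p 0.321). With the added offset this list was called higher, with a median of 0.14 (camera adjusted p 0.0147) and 0 of 30 genes called by edgeR.

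The largest increases were Pla2g4e (2.48, SE 0.41), the zinc finger gene Zfp992 (1.99 ± 0.247 CPM against 0.443 ± 0.114), Erich5 (1.91), Xaf1 (1.67), Eno1b (70.4 ± 3.03 CPM against 24.8 ± 3.12), AA465934 (SE 0.37, adjusted p 0.0078), the iron reductase gene Cybrd1 (1.44), Gzmk (1.33), Cyp2a5 (1.29) and Fxyd2 (1.08). Some of these varied within genotypes. Pla2g4e was at 7.46 and 6.48 CPM in Q140 with Alfy homo F1 and M2 and at 29.2 or more in the rest of that group. Xaf1 ran from 5.83 to 27.4 CPM in wild type and from 5.16 to 23.4 in Q140. Besides Egr2 and Crocc, the largest decreases were Zfp984 (-3.01, SE 0.30), Xlr3b (-1.89), the fructose transporter gene Slc2a5 (-1.63), Mybpc1 (-1.53), Mamdc2 (-1.51), Bub1b (-1.48), Rsg1 (-1.40) and Megf6 (-1.34). Zfp984, Zfp992, Slc2a5, Rsg1, Megf6 and Crocc lie on chromosome 4, and Eno1b (chromosome 18) is a close paralog of Eno1 there, so reads of this pair are uncertain. In the window from 140 to 150 Mb of chromosome 4, 58 of 132 genes were called, 29 higher and 29 lower (43.9%, against 13.3% elsewhere, odds ratio 5.13, adjusted p 2.29e-15 by Fisher's exact test, one-sided), a window chosen after the data were seen. The length slope averaged -0.0249 ± 0.0389 against 0.0234 ± 0.0178 in Q140 (exact permutation p 0.00186), and with the offset 1973 genes were called, 1607 of them among the 2780 in the same direction. Without Q140 M3 the count was 1702, without Q140 with Alfy homo M1 it was 1399, and in females alone it was 96 against 1455 in males alone.

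**Figure D4:**
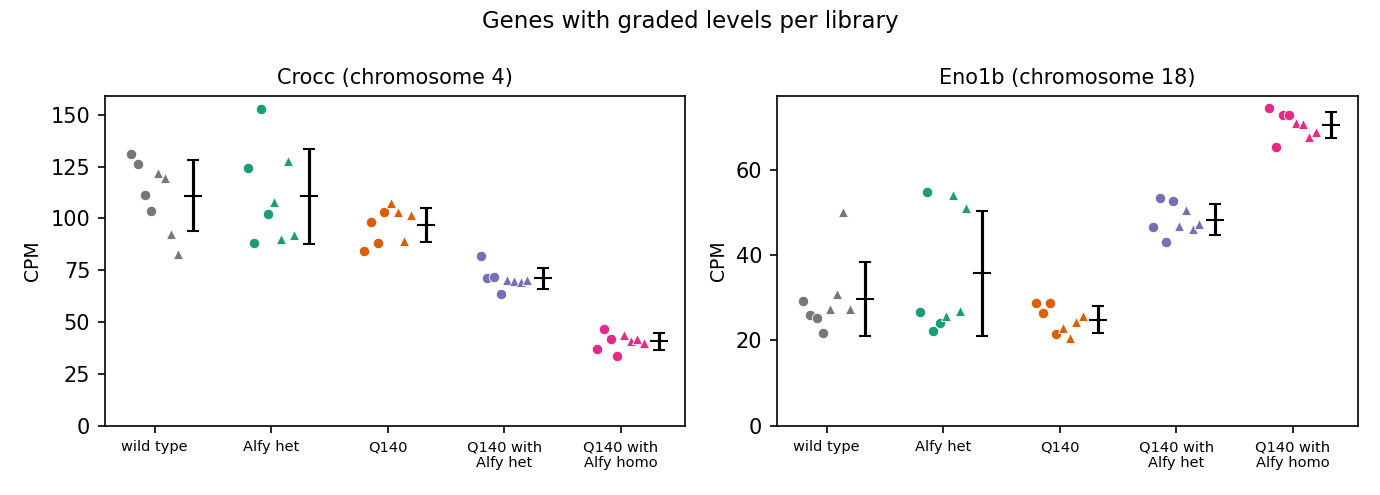
Levels of Crocc and Eno1b in CPM for each library by genotype, with circles for females, triangles for males, and the mean and SD of 8 libraries. Crocc averages 96.9 CPM in Q140, 71.0 in Q140 with Alfy het and 40.7 in Q140 with Alfy homo, and Eno1b 24.8, 48.3 and 70.4.

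Q140 with Alfy het was compared with Q140 to ask the same for the heterozygous Alfy genotype. Endothelial and protocadherin genes were lower by camera at its preset correlation, and none of the 30 shared projection neuron genes was called. With an estimated correlation these 2 lists had adjusted p = 0.0693 and adjusted p = 0.517. Abcb1a (-0.47, SE 0.07), Kdr, a receptor of vascular endothelial growth factor (-0.66, SE 0.12), Flt1 (-0.36) and Cdh5 (-0.36) fell, and Flt1 averaged 60.0 ± 8.28 CPM against 77.1 ± 6.71 (SD, n = 8). The edgeR fit called 381 genes, 175 higher and 206 lower.

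Of 10 endothelial genes 4 fell (8 adjusted over the list alone), with adjusted p 6.01e-10 by camera. Blood genes were lower beside them (2.07 ± 0.49 log2 CPM against 2.63 ± 0.33, n = 8), with 0 of 5 called by edgeR (2 adjusted over the list alone), camera adjusted p 0.00295 and adjusted p = 0.517 with an estimated correlation. Clustered protocadherins fell in 4 of 58 (23 fell and 1 rose adjusted over the list alone): Pcdhb2 (-0.82), Pcdhga4 (-0.56), Pcdhb21 (-0.48) and Pcdhgc5 (-0.41), with adjusted p 3.48e-13 and adjusted p = 0.517 with an estimated correlation. Of 40 oxidative phosphorylation genes Sdhb rose (0.13; 2 adjusted over the list alone), with adjusted p 2.52e-06, adjusted p = 0.517 with an estimated correlation and adjusted p 0.949 with the added offset. Of 31 proteasome genes Psma7 rose (0.13; 1 adjusted over the list alone), with adjusted p 0.00418, adjusted p = 0.796 with an estimated correlation and adjusted p 0.897 with that offset. Myelin genes had a median of 0.19 with 0 of 14 called by edgeR, for example Opalin at 0.51 (adjusted p 0.104). Microglial genes had a median of -0.14 with 0 of 13 called, for example Csf1r at -0.20 (adjusted p 0.074). These lists had camera adjusted p 0.000411 and 0.00418, and both adjusted p = 0.517 with an estimated correlation. Astrocyte genes averaged 7.30 ± 0.11 log2 CPM against 7.45 ± 0.05 in Q140 (n = 8), with 0 of 11 called by edgeR (3 adjusted over the list alone), camera adjusted p 0.00418, adjusted p = 0.517 with an estimated correlation and 0.116 with that offset. Camera at its preset correlation also called ependymal (adjusted p 0.00664) and cholesterol synthesis genes (0.0200) higher, and striosome (0.0462), receptor (0.00189) and cAMP signalling genes (0.0200) lower, with 0 members called by edgeR. With an estimated correlation these had adjusted p = 0.517, except cholesterol synthesis (adjusted p = 0.789), and with the offset the call remained for cholesterol synthesis alone (adjusted p 0.0335).

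The largest increases were Masp2 (1.93, SE 0.49), AA465934 (1.70), Xaf1 (1.39), Fxyd2 (1.18), Eno1b (0.96), Rgs22 (0.81), Vwa7 (0.80), Crybg2 (0.76), Tekt1 (0.69) and Cenps (0.68). Masp2 was at 0.737 CPM in Q140 with Alfy het F4 and at 3.28 or more in the rest of that group. The largest decreases were Mamdc2 (-1.68, SE 0.37), Slc2a5 (-0.92), Pcdhb2, the GABA transporter Slc6a13 (-0.82), Scube2 (-0.72), Gcnt1 (-0.72), Olfr287 (-0.67), Slc25a34 (-0.66), fibronectin Fn1 (-0.66) and Kdr. The window from 140 to 150 Mb of chromosome 4 held 24 calls among 132 genes (18.2%, against 1.75% elsewhere, odds ratio 12.5, adjusted p 7.66e-15 by Fisher's exact test, one-sided). Long transcripts were lower here too (rho -0.378), with a mean length slope of -0.0168 ± 0.0335 against 0.0234 ± 0.0178 (exact permutation p 0.0126, n = 8), and with the offset 220 genes were called. The count of 381 rested on single libraries: it was 191, 166, 787, 217, 95 and 166 without Q140 F1, F3, F4, M2, M3 and M4, and 119, 134, 938, 187, 247, 989 and 148 without Q140 with Alfy het F1, F3, F4, M1, M2, M3 and M4. It was 88 when only the 16 libraries compared were fitted, 862 by DESeq2, 35 in males alone and 9 in females alone.

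Between the 2 Alfy genotypes on Q140, the immediate early list was lower and the microglial list higher in Q140 with Alfy homo by camera at its preset correlation. Only 1 of 18 and 1 of 13 members were called, and with an estimated correlation adjusted p = 0.146 and adjusted p = 0.144. The edgeR fit called 162 genes, 69 higher and 93 lower. The immediate early list (13 fell adjusted over the list alone) had a median of -0.61 and adjusted p 4.74e-13 by camera. The microglial list (10 rose adjusted over the list alone) had a median of 0.18 and adjusted p 2.14e-09. Genes encoded in mitochondria were higher (adjusted p 2.14e-09), and cholesterol synthesis (2.83e-07), chaperone (0.00235) and ependymal genes (0.00275) lower, by camera with 0 members called by edgeR (10 mitochondrial and 4 cholesterol synthesis genes adjusted over the list alone). With an estimated correlation these 4 had adjusted p = 0.146, 0.378, 0.836 and 0.754. The genes with the smallest p were Setmar (0.51), Fam227b (2.69), Exd1 (0.81), Ssb (0.44) and Rhno1 (0.27) among those that rose, and Nat8f5 (-2.41), Crocc (-0.80), Zfp984 (-2.52), Hnrnpa3 (-0.42) and Slc38a6 (-1.15) among those that fell. The window on chromosome 4 held 19 of these calls (odds ratio 24.2, adjusted p 1.48e-16 by Fisher's exact test, one-sided).

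The Alfy effect was compared between backgrounds. Across 15536 genes, the change in Alfy het against wild type correlated with that in Q140 with Alfy homo against Q140, with which it shares no library, at r 0.579 and rho 0.699, and 211 genes were higher and 334 lower in both where 30.3 and 40.5 were expected by chance. Both changes go with transcript length (rho -0.339 and -0.395), which makes them correlate, so this overlap is not a measure of the Alfy effect alone. For the heterozygous genotype in both backgrounds, again with no shared library, the correlation was lower (r 0.421, rho 0.524), with 33 genes higher and 64 lower in both. The interaction of Q140 and Alfy het called 1 gene by edgeR, the kinase gene Pim3 (log2 difference 0.53, SE 0.09, adjusted p 0.0184), and 26 by DESeq2. Pim3 was lower in Q140 than in wild type (-0.21, adjusted p 0.0386) and higher in Q140 with Alfy het than in Q140 (0.33, adjusted p 0.00608), and it was named after its values were seen. The interaction called 0 genes by edgeR without the 3 libraries that stood apart, in males alone and in females alone (1250, 1402 and 884 genes with an unadjusted p under 0.05), and 6 of 100 splits of the libraries gave as many calls, so chance is not excluded. The interactions with sex called 0 genes by edgeR for Q140, for Alfy homo on Q140 and for Alfy het on Q140. There 448, 950 and 879 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene in each.

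Whether Alfy overexpression moves the Q140 profile back toward wild type was asked with genes and with scores. Projection neuron genes averaged 8.60 ± 0.10 log2 CPM in wild type, 8.14 ± 0.21 in Q140, 8.16 ± 0.23 in Q140 with Alfy het and 8.21 ± 0.18 in Q140 with Alfy homo (SD, n = 8). Penk averaged 699 ± 134 CPM in Q140 with Alfy het and 754 ± 114 in Q140 with Alfy homo, against 663 ± 116 in Q140. The score for Q140 with Alfy homo used 1820 genes and was lower than in Q140 by 0.0357 of a gap of 0.246 between Q140 and wild type (-14.5%, 95% interval of the difference -0.0711 to 0.00319, exact permutation p 0.108, n = 8), with all 8 libraries below the Q140 mean. With the 200 genes of smallest p the exact permutation p was 0.0278, and without Q140 F1 or F2 it was 0.0416 or 0.0182. With the median over genes in place of the mean the difference was -0.0160 (-8.81% of the gap, exact permutation p 0.311, n = 8), with 5 of 8 libraries below the Q140 mean. The score for Q140 with Alfy het used 6110 genes from Q140 with Alfy homo against wild type, which hold Alfy effects too, and was higher than in Q140 by 0.108 (exact permutation p 0.000155, the smallest these splits can give, n = 8). On this score the Alfy het libraries without Q140 ran from -0.0677 to 0.0733. All lay above every wild type library (-0.146 or less), and Q140 averaged -0.0350. The rise is therefore not a measure of the Q140 change alone. With genes from Q140 with Alfy homo against Alfy het, an alternative added after seeing the data, the score for Q140 with Alfy het was higher than in Q140 by 0.0338 (exact permutation p 0.0844).

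**Figure D5:**
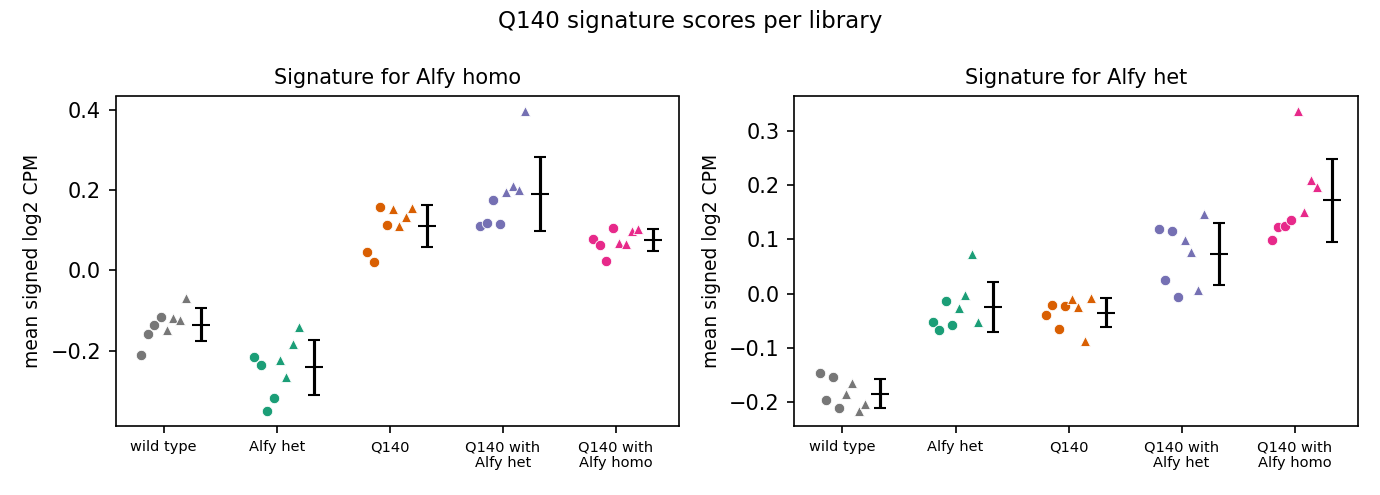
Mean signed log2 CPM of the signature genes for each library by genotype, with circles for females, triangles for males, and the mean and SD of 8 libraries, where a higher score is further from wild type. Left are the 1820 genes called in Q140 with Alfy het against Alfy het, and right the 6110 genes called in Q140 with Alfy homo against wild type, so these groups are apart by construction.

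Of the 1263 genes called in Q140 against wild type, 116 moved back and 67 moved further in Q140 with Alfy homo, where 85.0 and 84.8 were expected by chance. In Q140 with Alfy het 28 moved back and 5 further, where 11.6 and 11.7 were expected. Among those that moved back were Vwa7 (-1.61 in Q140, 0.80 and 0.71 with Alfy het and Alfy homo), Pcdh20 (0.67, then -0.46 and -0.43) and, in Q140 with Alfy homo, Ptpn7 (-1.26, then 0.61). Gm6089 (2.74, then -2.96), Gm5067 (0.83, then -1.13) and Gm21168 (1.10, then -1.11) also moved back with Alfy homo. These predicted genes, chosen after their values were seen, lie close together on chromosome 5 within 10 Mb of Htt. Whether a chromosome segment that differs between the groups accounts for them was not tested. The comparisons with wild type and with Alfy share the Q140 libraries, which favours opposite signs. When a sex-balanced part of the Q140 libraries gave the signature and the other part the comparison, the change averaged -2.22% of the gap (range over 36 splits -12.9 to 15.7) with Alfy het and -5.70% (range -16.3 to 11.9) with Alfy homo.

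Both Alfy genotypes on Q140 were also compared with wild type, to ask what differs from wild type when both alleles are present. In Q140 with Alfy het 4495 genes were called, 2311 higher and 2184 lower, and in Q140 with Alfy homo 6110, 3322 higher and 2788 lower. Both changes go with transcript length (rho -0.321 and -0.345), so these counts are not a measure of the 2 alleles alone. With the added offset for length and GC content 4130 and 5723 genes were called. Of these, 3330 and 4643 were among the calls without the offset, in the same direction. Tnnt2 (0.86 and 1.01), Nagk (0.51 and 0.59), Tmub1 (0.37 and 0.46), Bscl2, which encodes seipin (0.26 and 0.32), and Npr2 (0.32 and 0.40) had the smallest p among genes that rose in both. Among those that fell were Ryr1 (-1.31 and -1.64), and Mafa (-2.55), Slc4a11 (-1.52), Neto2 (-0.75) and Ddit4l (-1.19) with Alfy het, and Crocc (-1.45), Zfp982 (-2.82), the integrin gene Itga6 (-0.83) and Rsg1 (-1.44) with Alfy homo.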

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

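All tests of explanations in this part were chosen only after the result they test was seen. In 10 of 75 groups of 8 libraries tested, a library lay far from the nearest of the others, where chance gives about 1 in 20. For Wdfy3 this was Q140 with Alfy homo M1 at 156 CPM. For Htt it was wild type M4 at 205 CPM and Q140 with Alfy homo M1 at 128 CPM. For single genes it was Pla2g4e in wild type M2 (27.2 CPM), Crocc in Q140 with Alfy het F1 (81.8 CPM), Eno1b in wild type M3 (50.02 CPM) and AA465934 in Q140 with Alfy homo M2 (14.8 CPM). For the signature scores it was Alfy het M3 (0.0733) and Q140 with Alfy homo M1 (0.335) in the score used for Alfy het, and Q140 with Alfy het M4 (0.396) in the score used for Alfy homo. For Pim3 the Alfy het effect differed between backgrounds by 0.53 (interaction by edgeR, SE 0.09, adjusted p 0.0184), a call that ended without the 3 libraries that stood apart and in each sex alone.

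Wdfy3 was not higher in the 24 libraries labelled with Alfy overexpression. No library stood out: the highest of the 40 libraries had 302 CPM, 1.29 times the median. Swapped labels would leave some libraries with clearly higher Wdfy3 only if the construct adds to these counts. Since that is not known, this test cannot decide on a swap. With the offset for transcript length and GC content the log2 change in Q140 with Alfy homo was -0.19 (SE 0.04, adjusted p 0.00682 by edgeR). That offset is a smooth fit over all genes, so it can leave part of the trend in a single gene. Among libraries with length slopes near 0, Wdfy3 was at 220 and 230 CPM in Q140 F4 and M1 (slopes -0.0026 and -0.0014). It was at 232 and 228 CPM in Q140 with Alfy homo F3 and F4 (slopes 0.0066 and 0.0091). Whether the trend accounts for all of the decrease is therefore not decided. Whether the construct carries the part of the transcript that these counts cover is not given in the sources used here and stays open. No biological explanation was tested.

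Calls in Q140 with Alfy homo against Q140 were dense on chromosome 4 from 140 to 150 Mb (odds ratio 5.13 in a window found in these data). The length and GC trend is argued against, as the odds ratio after the offset was 7.16. A chromosome segment that differs between the animals of the groups may be a source, with Crocc at 96.9, 71.0 and 40.7 CPM in Q140, Q140 with Alfy het and Q140 with Alfy homo. An effect of the Alfy allele in any background stays open: in Alfy het against wild type the odds ratio was 1.19 (95% interval 0.503 to 2.44), and 2.88 (1.39 to 5.37) after the offset, while Crocc averaged 111 ± 17.03 CPM in wild type and 111 ± 22.8 in Alfy het. Eno1, just beyond the window and chosen after its values were seen, differed within Alfy het. It was at 151, 145 and 144 CPM in F2, M2 and M4 and at 186 or more in the rest. Wild type M3, without Alfy, was at 135 CPM. Without Q140 the level of Eno1 thus did not follow the Alfy label, though reads of Eno1 and Eno1b are uncertain. For the genes of the window as a set, a segment and an allele effect cannot be told apart without genotypes of the animals. These are not given in the sources used here.

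Of the 2780 calls in Q140 with Alfy homo against Q140, 1607 were kept in the same direction after the length and GC offset and 2570 with the covariate of cortical markers, so neither the length trend nor cortical tissue in the dissection accounts for all of them. For the 1173 calls that ended with the offset the median size of the change went from 0.20 (SD 0.18) to 0.12 (SD 0.18) and the median SE from 0.06 to 0.05, so these calls ended because the change shrank. The ratio of the change after to before had a median of 0.643 (quartiles 0.478 and 0.780), and for these genes the trend and an effect of genotype cannot be told apart, because the trend goes with the groups. RNA quality that differs between the groups may be a source of the trend (exact permutation p 0.00186 for the slopes, n = 8), and no measure of RNA integrity is given in the sources used here. An effect of the Alfy genotype on long transcripts stays open as untested.

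Counts of calls were compared with other splits of the libraries compared, 100 for each comparison with the real split included. Splits with as many calls numbered 1 for Q140 against wild type (real 1153, highest other 206), 1 for Alfy het against wild type (1539, 386), 1 for Q140 with Alfy homo against Q140 (1953, 4), 1 for Q140 with Alfy het against Alfy het (1276, 204), and 1 each for Q140 with Alfy het (3670, 2544) and Q140 with Alfy homo against wild type (5504, 2644). The number was 2 for Q140 with Alfy het against Q140 (88, 401) and 2 for Q140 with Alfy homo against Q140 with Alfy het (125, 1478), and these other splits, with several times the real count, point to a structure of the samples. In the first 40 splits drawn the last comparison also had 2, a share of 0.05, at which chance is not excluded, and the number of splits was raised to 100 for all comparisons after this was seen. No conclusion on chance is drawn for that comparison, nor for Q140 with Alfy het against Q140, where another split gave 401 calls against 88. Where the number of such splits was 1, no other split drawn reached the real count, which argues against chance for those counts. For the interaction of Q140 and Alfy het 6 of 100 splits had as many calls (real 1, and the highest other gave far more), so chance is not excluded.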

How the results depend on the processing

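The alternatives with an offset, a covariate, 3 libraries removed, a further signature or part of the Q140 libraries, those for Alfy and sex, and those for the interaction of Q140 and Alfy het in each sex alone or with no sex term, were chosen after seeing the data. Called named genes kept their direction under all alternatives that tested them. Of 237 called named genes DESeq2 kept 237, the length and GC offset 202, males alone 124 and females alone 72. For named genes that were not called, a change of direction was counted only where an alternative called them. Where a value below differs, the cause was not tested, except that single sexes leave 4 libraries per group.

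Genes called by edgeR with only the libraries compared were 88 for Q140 with Alfy het against Q140. DESeq2 called 1629 for Alfy het against wild type, 862 for Q140 with Alfy het against Q140, 249 for Q140 with Alfy homo against Q140 with Alfy het, 26 for the interaction of Q140 and Alfy het, and 1, 1 and 1 for the interactions of sex with Q140, Alfy homo on Q140 and Alfy het on Q140. With no filter the counts were 596 for Alfy het against wild type, 185 for Q140 with Alfy het against Q140 and 1 for Q140 and sex. With no sex term Q140 with Alfy het against Q140 gave 248. With the replicate block the interaction of Q140 and Alfy het gave 2, and no other count moved by over 1.5 times. In males alone the counts were 195 for Q140 and 59 for Alfy het against wild type, 35 and 1455 for Q140 with Alfy het and Alfy homo against Q140, 73 between these, 914 for Q140 with Alfy het against Alfy het, 1634 for it against wild type, and 0 for the interaction. In females alone they were 193, 8, 9, 96, 32, 461, 557 and 0, and 782 for Q140 with Alfy homo against wild type. With the length and GC offset Alfy het against wild type gave 640 and Q140 with Alfy het against Q140 gave 220. For the latter the cortical covariate gave 735 and removal of 3 libraries 163, and that removal gave 2726 for Q140 with Alfy het against wild type and 0 for the interaction.

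With each library left out in turn the counts ran from 953 to 1230 for Q140 against wild type, 339 to 1607 for Alfy het against wild type, 95 to 989 and 1399 to 2967 for Q140 with Alfy het and Alfy homo against Q140, 129 to 187 between these, 1284 to 1897 for Q140 with Alfy het against Alfy het, and 3467 to 4866 and 4952 to 6050 for Q140 with Alfy het and Alfy homo against wild type. The score for Alfy homo ran from -0.0486 to -0.0284 and was -0.0988 with 200 genes and -0.0160 with the median over genes. The score for Alfy het ran from 0.0971 to 0.119, and was 0.175 with 200 genes, 0.0338 with the further signature and 0.0256 with that signature and the offset. With parts of the Q140 libraries, genes moving back numbered 4 and 1 (Alfy het) and 24 and 14 (Alfy homo), against 1 and 0, and 22 and 6, moving further.

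Lists called by camera with an estimated correlation were 2 for Q140 against wild type and 0 for the other 7 comparisons of genotypes, and by fry 6 for Q140 and 1 for Alfy het against wild type, 2 and 2 for Q140 with Alfy het and Alfy homo against Q140 and 3 between these, where the preset correlation gave 18, 9, 13, 8 and 6. With the offset 7 lists were called for Q140 with Alfy het against Q140.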

Other observations

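In Q140 with Alfy homo against wild type, 26 of 40 nuclear genes of oxidative phosphorylation rose and none fell (camera adjusted p 3.55e-09, adjusted p = 0.471 with an estimated correlation, and adjusted p 0.0707 with the length and GC offset, which ends the call), and 18 of 31 proteasome genes rose and none fell (adjusted p 1.63e-05, adjusted p = 0.543 with an estimated correlation). With the offset 22 of the 40 oxidative phosphorylation genes still rose and 0 fell, with a median of 0.11. Immediate early genes fell in 9 of 18 (adjusted p 1.47e-06, adjusted p = 0.383 with an estimated correlation). Of 31 core autophagy genes 12 rose and 4 fell, and camera did not call the list (adjusted p 0.142) but called it higher with the offset (adjusted p 0.00973). These lists were singled out after the data were seen.

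Calls in Alfy het against wild type were also dense on chromosome 11 from 80 to 90 Mb, where 22 of 125 genes were called (odds ratio 4.01, adjusted p 9.79e-05 by Fisher's exact test, one-sided), with 10 of 125 in Q140 with Alfy het against Q140 (odds ratio 4.70) and an odds ratio of 1.61 in Q140 with Alfy homo against Q140. This scan of windows, added after the data were seen, called 4 more windows in Alfy het against wild type, on chromosome 17 from 20 to 30 Mb (27 of 224, odds ratio 2.57), 7 from 10 to 20 Mb (19 of 135, 3.07), 19 from 20 to 30 Mb (11 of 62, 4.02) and 9 from 40 to 50 Mb (14 of 103, 2.93), with adjusted p 0.00453 to 0.0416. The windows on chromosomes 17 and 7 were also dense in Q140 with Alfy het against Alfy het (55 of 224, odds ratio 3.44, adjusted p 4.42e-10, and 31 of 135, odds ratio 3.12, adjusted p 7.55e-05), the comparison that supplies the 1820 signature genes. In Q140 against wild type the scan called chromosome 18 from 30 to 40 Mb (26 of 179, odds ratio 2.63). Clustered protocadherins, several of which were called in that comparison, also lie on chromosome 18. Their share of the calls in this window was not counted, so it need not be a separate result. The scan called X from 130 to 140 Mb in that comparison too (13 of 68, 3.64). Q140 with Alfy homo against Q140 had calls dense on chromosome 2 from 120 to 130 Mb as well (36 of 142, 2.20). Chromosomes 15 from 30 to 40 Mb (18 of 56, 3.06) and 7 from 140 to 150 Mb (28 of 107, 2.29) were called there too. Several more windows were called between the 2 Alfy genotypes. AA465934, chosen after its values were seen, was at 7.06 CPM or more in 24 of 24 libraries labelled with Alfy and at 7 CPM or more in 5 of the 16 others, the rest being at 2.66 CPM or less. Gm4735, chosen after its values were seen, averaged 29.8 CPM in Q140, 15.7 in Q140 with Alfy het and 0.2498 in Q140 with Alfy homo, and lay from 15.7 to 17.7 CPM in 3 Alfy het libraries and at 29.96 or more in the other 5. Choroid plexus genes averaged 2.66 log2 CPM in Alfy het F1, where the group averaged 0.30, and cortical markers varied within groups, with an SD of 0.65 to 0.82 log2 CPM.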
